A study of Mus musculus with 6 samples.

How the data were processed

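Total RNA from mouse embryonic fibroblasts of the C57Bl/6NCr strain was isolated with a column kit and converted to biotin-labelled cRNA for Illumina bead arrays, per the labels' protocols. The labels give 3 arrays of Lasp1+/+ cells (wild type) and 3 of Lasp1-/- cells (Lasp1 knockout), numbered 1 to 3 in each group. The authors' deposited values are probe intensities on a linear scale. In the deposited table every array has a median intensity of 1000 over 45281 probes, and within each array every value is a whole multiple of a single step (100% within 0.05 of a step, with 1130 to 1326 steps in the median), so each array had been scaled by a single factor. The scanner, the software, the handling of the background and the summary of beads are not given in the sources used here. The smallest deposited value was 593 and the largest 557140. The lower part of the probes lay between 593 and 1000, which is the range of background light, so the values had not been background subtracted to 0 and the fold of a dim gene understates its change. Between 25.1% and 27.0% of probes exceeded 2000 in each array. Arrays give no counts, and precision was limited by their number.

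Probes were named from the platform annotation supplied with the table. Of the probes, 34885 had 1 gene symbol, 18 had several and 10378 had none there, and the last 2 kinds were left out of the gene tests. The Entrez identifier of 34807 probes was found in a RefSeq gene table of assembly GRCm38.p6, and 0 symbols needed an update. That table was used for names only, since no genome build is given in the sources used here, and coordinates were not analysed here. A gene was represented by the probe with the highest mean over the 6 arrays, which left 19057 genes.

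Values were transformed to log2 without a further normalization, because all array medians were equal, and fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend, 4 residual and 5.13 prior degrees of freedom) over all 6 arrays, with genotype as the only term. Log2 differences are knockout minus wild type, with their moderated standard error. P-values were two-sided and adjusted by Benjamini-Hochberg over all genes, with 0.05 as the threshold, and a log2 difference of 1 marked a 2-fold change. For the Lasp1 probes an exact permutation test of the mean difference was added. The 29 gene lists, with 1034 entries of which 943 were measured, were written before the data were examined. Each was tested against all other genes with camera (preset inter-gene correlation 0.01, Benjamini-Hochberg over the lists), and its members were counted by the gene test over all genes and adjusted over the list alone. Camera with a correlation estimated from the data, camera on ranks, and fry were run beside it. The design, the lists and the rule for named genes were fixed before the data were examined. That rule took Lasp1, the 12 largest rises and 12 largest falls among called genes with separate groups and a mean above the median of all probe means in at least 1 group, up to 3 rises and 3 falls per list by the same criteria, and as checks the sex genes and the 5 flanking genes with the smallest p. The 21 called gene models without a proper name were counted but not named. Members outside this rule that are named to complete a count (Plau, Plaur, Pdlim5, Pdlim7, Sox6, Krt8, Krt19, Cyp51, Ankrd37 and the called Hox genes) were chosen after their values had been seen.

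The gene and list tests were tested on simulated data made from the means and spread of these arrays, with 19057 genes. For the comparison of Lasp1 knockout with wild type, 61.2% of genes changed by 0.5 on the log2 scale, 97.0% of those changed by 1 and 100% of those changed by 2 were called, and 4 of 18845 unchanged genes were called. A list shifted by 0.5 was called and 0 of 28 unshifted lists were called, with genes simulated as independent of each other.

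Alternatives fixed before the data were examined were quantile normalization, centring of each array on its median, floors of 4, 16 and 64 before log2, a restriction to genes above the median of all probes, eBayes with trend and robust estimation (statmod 1.5.0), array weights, the mean of all probes of a gene, the replicate number as a block, and leaving out each array in turn. Background correction by limma's normexp method with an offset of 50 was added after the data had been seen. The genotype labels were also reassigned over all 10 splits of the 6 arrays into 3 and 3.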

Results

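Genome-wide RNA levels were measured in mouse embryonic fibroblasts, the connective tissue cells that grow out when an embryo is dissociated and placed in culture. The cells carried either 2 intact copies of Lasp1 (wild type) or a disrupted gene on both chromosomes (Lasp1 knockout), on the C57Bl/6NCr background. LASP1 is a LIM and SH3 domain protein that binds actin filaments and is found at focal adhesions and at the cell edge. Each genotype was represented by 3 Illumina bead arrays, 6 in all, and the series title places the comparison in the context of migration and tumour formation. The labels do not state that the arrays came from separate cultures or embryos, so all p-values measure the spread between these samples, which may be technical. Every array had a median intensity of 1000, and the upper quartile ranged from 2018 in knockout replicate 2 to 2330 in wild type replicate 2. Spearman's correlation between arrays was 0.914 to 0.925 within wild type, 0.916 to 0.924 within knockout and 0.904 to 0.927 between genotypes. In a principal component analysis of 11985 genes, component 1 held 57.8% of the variance and separated the genotypes, with wild-type scores of -10.2 to -20.2 and knockout scores of 12.1 to 18.5. Component 2 held 27.1% and ran from wild type replicate 2 (-14.1) and knockout replicate 1 (-13.8), the arrays with the highest upper quartiles, to wild type replicate 1 (16.6), with the other arrays at 0.709 to 6.13.

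Lasp1 was lower in every knockout array at both of its bright probes. At the brightest probe (ILMN_2879746) the wild-type arrays read 135295, 148208 and 148809, with a mean of 144104 ± 7634 (SD, n = 3), and the knockout arrays read 51904, 51019 and 49770, with a mean of 50898 ± 1072 (SD, n = 3). The gene therefore fell by 1.50 ± 0.07 (SE) on the log2 scale, or 2.83-fold, with an adjusted p of 1.17e-05 from limma. A dimmer probe (ILMN_2879745) read 12502 ± 1299 in wild type and 3097 ± 738 in knockout (SD, n = 3 each), a 4.10-fold difference with a limma adjusted p of 0.00018 over all probes. The dimmest probe (ILMN_2596851) read 1107 ± 58.2 and 923 ± 69.3 (SD, n = 3 each), close to the array median, and did not pass (limma adjusted p = 0.121). The exact two-sided permutation p was 0.1 for each probe, the smallest that 3 arrays against 3 allow. The signal at the brightest knockout probe remained at 35.3% of wild type and above 98.1% of all probes. Where the probes lie relative to the disrupted part of the gene was not determined here, and a probe outside that part does not check the genotype.

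**Figure D1:**
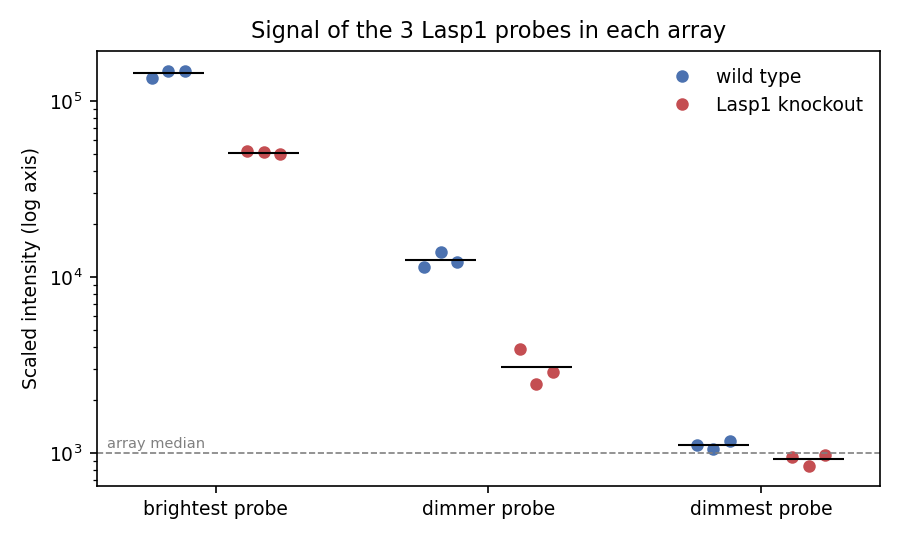
Intensity (log axis) of the 3 Lasp1 probes in the 6 arrays. Points are arrays, black lines are group means (n = 3) and the dashed line is the median of every array, 1000; the knockout arrays lie below the wild-type arrays at each probe, with means of 50898 against 144104 at the brightest.

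The comparison between genotypes asks which transcripts differ when Lasp1 is disrupted. Col2a1, the fibrillar collagen of cartilage, the methyltransferase Inmt, the cytokine antagonist Il1rn and the chemokine Cxcl1 rose in Lasp1 knockout fibroblasts. The R-spondin receptor Lgr5, the homeobox gene Msx1, the alcohol dehydrogenase Adh7 and the basal keratin Krt14 fell. Among 29 gene lists, 20 of 40 interferon response genes and 18 of 52 cell cycle genes fell, and of 58 Hox and positional genes 14 rose and 9 fell. The interferon and cell cycle lists passed limma's camera test with a preset correlation, but neither passed when it was estimated (adjusted p = 0.340 and 0.303 with an estimated correlation). The Hox and positional list passed neither (adjusted p = 0.261 and 0.807). Of 19057 genes, 418 rose and 778 fell at a limma adjusted p under 0.05, and 52 of the rises and 74 of the falls were at least 2-fold. The called genes were 6.28% of all genes tested, a share to set beside the count in each list. All 1196 of them had a mean above the median of all probes in at least 1 group. Restricted to the 11985 genes above that median over all arrays, limma called 1179, a larger share. That larger share is the closer comparison for lists made up mostly of bright genes. In all 1196 called genes the 3 knockout arrays lay entirely above or below the 3 wild-type arrays, which held for 21.3% of all genes against 10% by chance.

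The largest rise was in Col2a1, from an intensity of 1207 to 18307 (15.2-fold, log2 difference 3.92 ± 0.12 SE, limma adjusted p = 7e-07). Inmt, an enzyme that methylates amines, lay below the array median in wild type and is given no size. Kng1, the precursor of the kinins, rose by 2.62 ± 0.12 (6.14-fold). The transcription factor Sim2 rose 5.11-fold (2.35 ± 0.12). Il1rn, the antagonist of the interleukin-1 receptor, rose 4.75-fold (2.25 ± 0.09), and the acute-phase genes Lcn2, Serpina3n and Saa3 rose 4.21-fold, 3.84-fold and 3.66-fold. The neutrophil-attracting chemokine Cxcl1 rose 3.20-fold (1.68 ± 0.10). The homeobox gene Hoxa5 rose 3.70-fold (1.89 ± 0.13), the synuclein gene Sncg 3.68-fold (1.88 ± 0.10) and the alkaline ceramidase Acer2 3.30-fold (1.72 ± 0.11). The limma adjusted p of these 12 genes was at most 0.000145.

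The largest fall was in Lgr5, a receptor for R-spondins that strengthens Wnt signalling, from 14970 to 2388 (6.27-fold, log2 difference -2.65 ± 0.15 SE, limma adjusted p = 2.05e-05). Msx1, a homeobox gene of limb and face mesenchyme, was 6.16-fold lower (-2.62 ± 0.08), and Adh7, an alcohol dehydrogenase that also oxidises retinol, was 6.03-fold lower (-2.59 ± 0.12). Krt14, a keratin of basal epithelial cells, was 6.01-fold lower (-2.59 ± 0.11). The transcription factors Tfap2b and Bcl11b were 5.43-fold (-2.44 ± 0.08) and 3.74-fold (-1.90 ± 0.13) lower. Adipoq, the adipocyte hormone adiponectin, fell 4.05-fold (-2.02 ± 0.10), the membrane protein gene Tmem204 3.96-fold (-1.99 ± 0.11), the urea transporter Slc14a2 3.94-fold (-1.98 ± 0.14) and the lectin Chodl 3.59-fold (-1.84 ± 0.12). Isg15, a ubiquitin-like interferon-induced protein, and Usp18, the protease that removes it, were 3.87-fold (-1.95 ± 0.21) and 3.65-fold (-1.87 ± 0.17) lower. The limma adjusted p of these 12 genes was at most 0.000723. Because the intensities hold a background of similar size to the signal of dim genes, folds with a dim side were understated. A background correction added once the data had been seen raised the folds of Col2a1, Inmt, Lcn2, Saa3, Acer2, Tfap2b, Adipoq and Slc14a2 by over 1.5 times. It did the same for Fgf21, Sema3c, Lgals7, Plvap, Ibsp and Actc1, named below. The dim side of each lay within 1.5 times of the array median of 1000, so the size of these folds is not settled and their order is that of the deposited values.

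**Figure D2:**
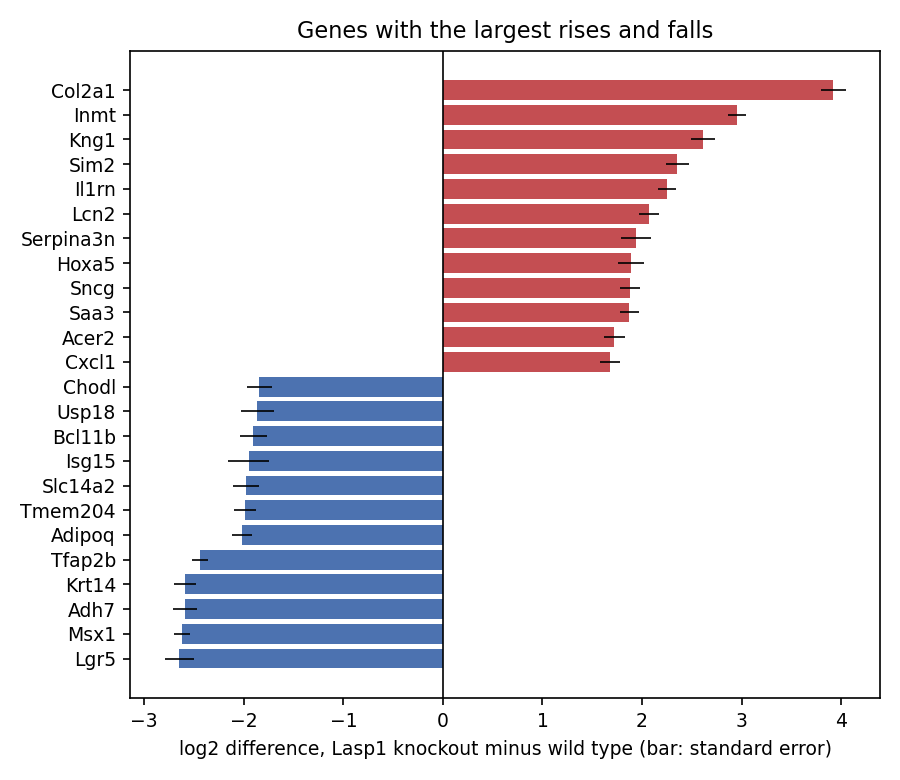
Log2 difference (knockout minus wild type) of the 12 genes with the largest rise and the 12 with the largest fall; bars are differences and whiskers 1 standard error (n = 3 arrays per genotype). The values run from 3.92 for Col2a1 to -2.65 for Lgr5, and the wild-type signal of Inmt lies below the array median.

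Of 40 measured interferon response genes, 20 fell and 20 did not pass, with 25 falls when adjusted over the list alone. Isg15, Usp18 and the oligoadenylate synthetase-like gene Oasl2 (-1.81 ± 0.16) led the falls, and the median log2 difference of the list was -0.46. Against all other genes the list was lower in limma's camera test (adjusted p = 5.56e-14), and it did not pass with the correlation between its genes estimated from the data (adjusted p = 0.340 with an estimated correlation). The number of falls was 11 without wild type replicate 3 and 11 without knockout replicate 3. Of 52 measured cell cycle genes, 18 fell and 34 did not pass, with 28 falls and 1 rise when adjusted over the list alone. The helicase subunits that license DNA replication led, with Mcm3 at -0.80 ± 0.11, Mcm2 at -0.77 ± 0.10 and Mcm6 at -0.74 ± 0.08, and the median of the list was -0.29 (camera adjusted p = 1.02e-13, adjusted p = 0.303 with an estimated correlation). The number of falls was 9 without knockout replicate 3. Top2a, the DNA topoisomerase of dividing cells, was called at its brightest probe (-0.58 ± 0.09), but 1 of its 3 probes went that way, and the mean over its probes did not pass (-0.03, limma adjusted p = 0.931, the highest of its alternatives, which began at 0.00025).

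**Figure D3:**
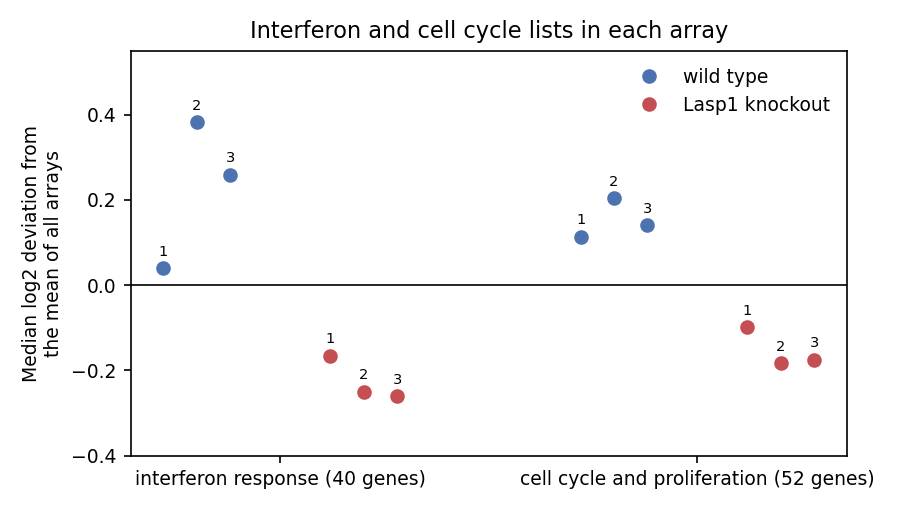
Median log2 deviation from the mean of the 6 arrays over the 40 interferon response genes and the 52 cell cycle genes; each point is an array, numbered by replicate. All knockout arrays lie below all wild-type arrays in both lists, and wild type replicate 1 (0.04) lies nearest to the knockout arrays (-0.17 to -0.26) for interferon genes.

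Chemokine and cytokine genes held more rises than falls among their called members. Among 37 measured, 9 rose, 2 fell and 26 did not pass, with 10 rises and 3 falls when adjusted over the list alone. Il1rn, Cxcl1 and Ccl9 (1.11 ± 0.09) rose, and Cxcl10, which interferons induce, and Ccl7 fell (-0.57 ± 0.07 and -0.42 ± 0.08). The camera adjusted p was 1.46e-06 upward (adjusted p = 0.104 with an estimated correlation), and the number of rises was 4 without wild type replicate 3, 4 without knockout replicate 3 and 5 without knockout replicate 2, with 1 fall in each of these. Secreted proteases and their inhibitors went both ways: of 38, 5 rose, 7 fell and 26 did not pass (6 and 10 when adjusted over the list alone), and the list did not pass camera (adjusted p = 0.968). Without knockout replicate 3 the counts were 3 and 4, and 3 rose without wild type replicate 3. The collagenase Mmp13 rose (1.25 ± 0.13), as did the plasminogen activators Plat (0.58 ± 0.07) and Plau (0.42 ± 0.08), the receptor Plaur (0.43 ± 0.10) and the inhibitor Timp1 (0.57 ± 0.09). Cathepsin K (Ctsk, -1.23 ± 0.13), Mmp11 (-1.08 ± 0.15) and the serine protease Htra1 (-1.01 ± 0.11) fell most.

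Of 45 collagen and fibrillar matrix genes, 13 fell, 1 rose and 31 did not pass, with 17 falls and 4 rises when adjusted over the list alone. The microfibril proteins Mfap4 (-1.45 ± 0.21) and Mfap5 (-1.15 ± 0.13) and the collagen chain Col1a2 (-0.84 ± 0.17) fell, and the small proteoglycan Ogn rose (0.49 ± 0.10). Camera gave an adjusted p of 0.000962 downward (adjusted p = 0.646 with an estimated correlation), and the number of falls was 4 without knockout replicate 3, 6 without wild type replicate 3 and 8 without knockout replicate 2, with 5 rises after quantile normalization and 5 without wild type replicate 2. Ogn was not called without wild type replicate 3, knockout replicate 1 or knockout replicate 2. Fibroblast identity genes fell in 10 of 28 cases and 18 did not pass, with 13 falls when adjusted over the list alone, among them Dpt (dermatopontin, -1.12 ± 0.12), the retinoic acid binding protein Crabp1 (-0.96 ± 0.10) and Col1a2, which both lists hold. Camera gave an adjusted p of 7.01e-05 (adjusted p = 0.429 with an estimated correlation), and the number of falls was 3 without knockout replicate 3, 3 without wild type replicate 3 and 4 without knockout replicate 2. Matricellular genes, which code for matrix proteins that act on cells, had 3 rises, 3 falls and 14 of 20 that did not pass (4 and 4 when adjusted over the list alone; camera adjusted p = 0.968), and 5 rises and 5 falls without wild type replicate 1. Smoc1 (1.51 ± 0.10), Mgp (0.58 ± 0.08) and Ccn2 (0.56 ± 0.07) rose, and Comp (-1.05 ± 0.16), Postn (-0.77 ± 0.08) and Ccn4 (-0.77 ± 0.07) fell.

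Smooth muscle and SRF target genes, part of the contractile programme of myofibroblasts, had rises only among their called members in the deposited scaling, against 11 rises and 2 falls after quantile normalization. Of 33 measured, 8 rose and 25 did not pass, with 8 rises and 2 falls when adjusted over the list alone. The smooth muscle actin Actg2 (0.79 ± 0.07), the actin nucleator Lmod1 (0.77 ± 0.07) and Tagln (0.63 ± 0.11) rose most. Camera gave an adjusted p of 5.49e-06 (adjusted p = 0.340 with an estimated correlation), and the number of rises was 4 without wild type replicate 3 and 5 without each of the knockout arrays, with 2 falls without knockout replicate 1 and 1 without wild type replicate 1. Of 56 actin cytoskeleton genes, 6 rose, 1 fell and 49 did not pass (7 and 5 when adjusted over the list alone; camera adjusted p = 0.224). The Ena/VASP family gene Enah, whose protein promotes actin filament elongation, rose by 1.10 ± 0.20, the myosin light chain Myl9 by 0.40 ± 0.09 and the actin depolymerising factor Dstn by 0.36 ± 0.09, while the formin Diaph3 fell (-0.37 ± 0.08). Limma called none of the 56 genes without wild type replicate 3 or without knockout replicate 3, 1 rise without knockout replicate 2, 1 rise and 3 falls without knockout replicate 1, and 4 rises and 2 falls without wild type replicate 2, against 13 rises and 8 falls at an unadjusted p under 0.05 with all arrays. The log2 differences stayed of similar size where the calls were lost: without wild type replicate 3 and without knockout replicate 3 they were 0.93 and 1.16 for Enah, 0.40 and 0.46 for Myl9, 0.34 and 0.40 for Dstn, and -0.40 and -0.34 for Diaph3. After quantile normalization 10 rose and 3 fell. Among 51 focal adhesion genes, 5 rose, 3 fell and 43 did not pass (8 and 4 when adjusted over the list alone; camera adjusted p = 0.0581). The counts were 2 and 1 without wild type replicate 3, knockout replicate 2 or knockout replicate 3, 2 and 4 without knockout replicate 1, 5 and 5 without wild type replicate 1, and 10 and 4 after quantile normalization. Integrin alpha 3 (Itga3, 0.78 ± 0.11), the syndecans Sdc2 (0.75 ± 0.09) and Sdc4 (0.55 ± 0.13), and Pdlim7 and Pdlim5 (0.39 ± 0.10 and 0.38 ± 0.08) rose, and talin 2 (Tln2, -0.87 ± 0.12), integrin beta 4 (Itgb4, -0.65 ± 0.13) and the kinase Ptk2b (-0.31 ± 0.07) fell. Of 12 LASP1 family members and binding partners, limma called Lasp1 and no other in the deposited scaling. It called 2 rises after quantile normalization, 2 with array weights and 1 without wild type replicate 1, wild type replicate 2 or knockout replicate 2. At an unadjusted p under 0.05, 3 others were higher, and adjusted over the list alone 2 rose and 1 fell (camera adjusted p = 0.35, with Lasp1 itself among the members). Of the 12, 6 had a mean above the median of all probes in at least 1 group, so a missing call says little about the rest. Cell adhesion and guidance molecules gave 2 rises, 8 falls and 40 of 50 that did not pass (6 and 10 when adjusted over the list alone; camera adjusted p = 0.974), and 9 rises and 9 falls after quantile normalization. Rises numbered 4 without wild type replicate 2 or knockout replicate 2 and 1 without wild type replicate 3, and without knockout replicate 3 the counts were 1 and 5. The guidance genes Sema5a (-1.15 ± 0.10) and Slit3 (-1.03 ± 0.10, with 2 of its 3 probes in that direction) and the cadherin Cdh3 (-0.99 ± 0.11) fell, and Sema3c (0.78 ± 0.11) and the ephrin receptor Epha2 (0.55 ± 0.11) rose.

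Positional genes, the transcription factors that mark where along the body a fibroblast arose, went in both directions. Of 58 measured, 14 rose, 9 fell and 35 did not pass, with 17 rises and 14 falls when adjusted over the list alone, and camera, which asks for 1 direction, did not pass (adjusted p = 0.261; the median of -0.03 and the test's upward direction differ in sign). Hoxa5, the forkhead gene Foxc1 (1.17 ± 0.13) and Hoxa2 (1.06 ± 0.10) rose most, and Msx1, Osr2 (-1.22 ± 0.09) and the hindlimb gene Tbx4 (-1.18 ± 0.09) fell most. The number of rises was 7 without wild type replicate 3, 7 without knockout replicate 3 and 9 without knockout replicate 1. The Hox genes differed by paralog group, a grouping made after the values had been seen. Of 19 measured Hox genes in groups 1 to 7, which are expressed from anterior levels of the embryo, 9 rose (Hoxa2, Hoxa3, Hoxa4, Hoxa5, Hoxa7, Hoxb5, Hoxb6, Hoxb7 and Hoxc6) with a median log2 difference of 0.36. Of 19 in groups 8 to 13, 4 fell (Hoxd8, Hoxc10, Hoxd12 and Hoxd13) with a median of -0.14. The called genes also differed by cluster, with rises in Hoxa, Hoxb and Hoxc and falls in Hoxc and Hoxd. Across these 38 genes, which lie in clusters and are not independent, Spearman's rho between paralog group and log2 difference was -0.53 (permutation p = 0.00086) and Pearson's r was -0.46 (permutation p = 0.00346, 100000 permutations each).

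**Figure D4:**
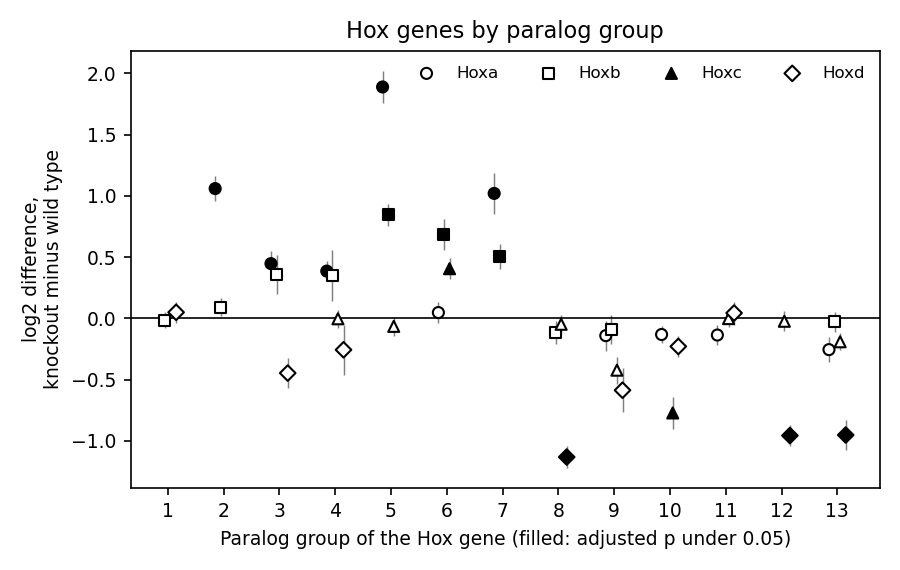
Log2 difference (knockout minus wild type) of 38 Hox genes against their paralog group; marker shapes give the cluster, filled markers have an adjusted p under 0.05 and whiskers are 1 standard error (n = 3 arrays per genotype). The 9 called genes in groups up to 7 lie above 0 and the 4 called genes in groups from 8 lie below it.

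Growth factors and their receptors changed in both directions. Among 61, 11 rose, 10 fell and 40 did not pass (13 and 15 when adjusted over the list alone; camera adjusted p = 0.634). The counts were 7 and 3 without wild type replicate 3, 7 and 4 without knockout replicate 3, and 9 and 3 without knockout replicate 2. The activin antagonist Fst (1.30 ± 0.12), Fgf7 (1.28 ± 0.11) and the BMP antagonist Grem1 (1.03 ± 0.13) rose, and Fgf21 (-1.33 ± 0.10), the lymphatic growth factor Vegfc (-1.17 ± 0.08) and the VEGF receptor Flt1 (-1.09 ± 0.21) fell. Flt1 was called at its brightest probe, but 1 of its 2 probes went that way, and its mean over both did not pass (limma adjusted p = 0.0967, with 0.000297 to 0.101 over its alternatives). Imprinted genes had 2 rises (Dlk1, 0.82 ± 0.12, and Igf2, 0.28 ± 0.07), 2 falls (Dcn, -0.64 ± 0.11, and Mest, -0.39 ± 0.09) and 17 of 21 that did not pass (6 and 3 when adjusted over the list alone; camera adjusted p = 0.0581). Rises numbered 4 after quantile normalization and 1 without wild type replicate 3 or any of the knockout arrays, and falls 1 without wild type replicate 3 or knockout replicate 2. Neither fall was called without knockout replicate 3.

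Markers of other cell types went in both directions. Of 21 chondrocyte and osteoblast genes, 4 rose, 2 fell and 15 did not pass (5 and 3 when adjusted over the list alone). Col2a1, Sox5 (1.62 ± 0.11), the bone sialoprotein Ibsp and Sox6 rose, whereas Comp and Sox9, the transcription factor that activates Col2a1 in cartilage, fell (-1.05 ± 0.16 and -0.47 ± 0.09). Ibsp and Sox6 lay below the array median in wild type and are given no size. Camera gave an adjusted p of 0.0209 upward, with a mean of 0.26 and a median of -0.01 (adjusted p = 0.340 with an estimated correlation). The camera adjusted p was 0.0644 after quantile normalization and 0.112 without wild type replicate 2. Fry, which does not compare the list with other genes, gave an adjusted p of 0.0023. The number of falls was 1 without wild type replicate 3, knockout replicate 2 or knockout replicate 3. Of 14 adipocyte genes, 3 fell (Adipoq, Lpl at -1.49 ± 0.12 and Lep at -0.29 ± 0.07) and 11 did not pass, with 3 falls when adjusted over the list alone (camera adjusted p = 0.00852, adjusted p = 0.340 with an estimated correlation). Lep lost its call whichever array was left out, and limma called it in 4 of 13 alternatives (adjusted p = 0.0113 to 0.164). Its intensity was 1327 in wild type and 1088 in knockout, near the array median. Epithelial genes fell in 5 of 22 cases (Krt14, Lgals7 at -0.91 ± 0.10, Krt7 at -0.87 ± 0.12, Krt8 at -0.71 ± 0.07 and Krt19 at -0.45 ± 0.11) and 17 did not pass, with 2 rises and 5 falls when adjusted over the list alone (camera adjusted p = 0.261). Of 21 macrophage and leukocyte genes, Lyz2 rose (0.56 ± 0.10), Lgmn fell (-0.45 ± 0.11) and 19 did not pass (3 and 1 when adjusted over the list alone). Camera placed that list upward (adjusted p = 0.00243, median 0.09, adjusted p = 0.399 with an estimated correlation), and 4 rose after quantile normalization and 5 without wild type replicate 2. Neither Lyz2 nor Lgmn was called without knockout replicate 3. Skeletal muscle genes rose in 2 of 19 cases, the striated actins Acta1 (1.52 ± 0.14) and Actc1 (below the array median in wild type and so given no size), and 17 did not pass (2 rises when adjusted over the list alone; camera adjusted p = 0.0581). Of 20 neural and glial genes, Nes rose (1.32 ± 0.11), Sox10 (-0.60 ± 0.14) and Mbp (-0.44 ± 0.10) fell and 17 did not pass (1 and 2 when adjusted over the list alone; camera adjusted p = 0.562). Neither fall was called without wild type replicate 3, knockout replicate 2 or knockout replicate 3. Of 17 endothelial genes, Emcn rose (0.62 ± 0.09), Plvap (-1.42 ± 0.11) and Eng (-0.52 ± 0.12) fell and 14 did not pass (1 and 4 when adjusted over the list alone; camera adjusted p = 0.634). Endothelial falls numbered 4 without wild type replicate 1 and 1 without wild type replicate 3 or any of the knockout arrays.

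Of 25 cholesterol and fatty acid synthesis genes, 4 fell (Acss2 at -0.75 ± 0.09, Mvd at -0.60 ± 0.12, Ebp at -0.54 ± 0.09 and Cyp51 at -0.53 ± 0.09) and 21 did not pass, with 7 falls when adjusted over the list alone (camera adjusted p = 0.000218, adjusted p = 0.399 with an estimated correlation). The number of falls was 2 without wild type replicate 3 and 2 without knockout replicate 3. Glycolysis and hypoxia genes gave 4 rises, 3 falls and 21 of 28 that did not pass (9 and 4 when adjusted over the list alone; camera adjusted p = 0.0581). Rises numbered 9 after quantile normalization, 7 without wild type replicate 1, and 1 without wild type replicate 3, knockout replicate 1 or knockout replicate 2. Without knockout replicate 3 the counts were 2 and 1. The glucose transporter Slc2a1 (0.52 ± 0.07), P4ha2 (0.37 ± 0.09), Pfkl (0.36 ± 0.07) and Ankrd37 (0.30 ± 0.07) rose, and Ndrg1 (-0.69 ± 0.10), the neuronal-type transporter Slc2a3 (-0.61 ± 0.11) and Car9 (-0.45 ± 0.07) fell. Of 33 p53 target and senescence genes, 3 rose (Mdm2 at 0.60 ± 0.08, Plk2 at 0.54 ± 0.11 and Fas at 0.51 ± 0.07), 3 fell (Igfbp3 at -0.81 ± 0.12, Cdkn2c at -0.71 ± 0.09 and Igfbp5 at -0.48 ± 0.12) and 27 did not pass (8 and 4 when adjusted over the list alone; camera adjusted p = 0.150). Rises numbered 8 after quantile normalization, 7 without wild type replicate 1 and 5 without wild type replicate 2, and falls 5 without wild type replicate 1. The antioxidant genes Gstm2 (-0.56 ± 0.10), Gclm (-0.46 ± 0.08) and Slc7a11 (-0.38 ± 0.09) were the called members among 29 NRF2 targets, with 26 that did not pass (1 rise and 5 falls when adjusted over the list alone; camera adjusted p = 0.968). Falls numbered 5 without wild type replicate 1 and 1 without wild type replicate 3, and none of the 3 was called without knockout replicate 2 or 3. Among 40 ribosomal protein genes limma called 0, against 1 higher and 1 lower at an unadjusted p under 0.05, and 2 rises after quantile normalization (0 when adjusted over the list alone; camera adjusted p = 0.503).

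**Figure D5:**
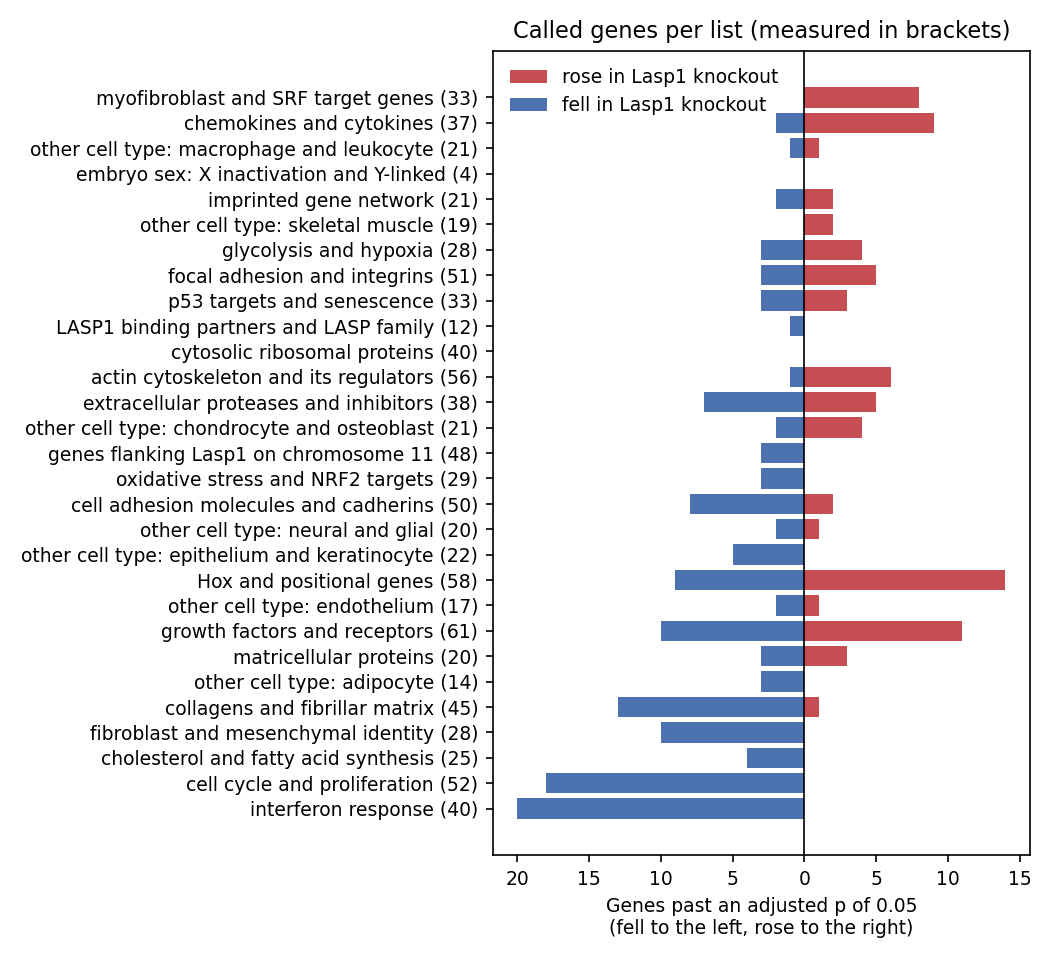
Number of genes in each of the 29 lists that rose (right) or fell (left) in the knockout arrays at an adjusted p under 0.05, ordered by the median log2 difference of the list, with the number measured in brackets. The plot shows 20 falls among 40 interferon response genes, 18 among 52 cell cycle genes, and 14 rises and 9 falls among 58 Hox and positional genes.

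Genes that flank Lasp1 on chromosome 11 and genes that tell the sex of the embryo were examined as checks. Of 48 flanking genes, 3 fell (Igfbp4 at -0.87 ± 0.16, Plxdc1 at -0.68 ± 0.11 and Top2a) and 45 did not pass, with 3 falls when adjusted over the list alone (camera adjusted p = 0.968). That count is near the 6.28% called over all genes, so it does not set the flanking genes apart. None of these 3 falls was called without knockout replicate 3 and 1 without wild type replicate 3, and after quantile normalization 3 genes rose and 4 fell. The next in order of p were Rara (-0.41 ± 0.12) and Rpl23 (0.53 ± 0.16), which did not pass (limma adjusted p = 0.0879 and 0.102). Both passed after quantile normalization (0.0109 and 0.0182) and with array weights (0.0038 and 0.00788), Rara in 5 of 13 alternatives (0.0038 to 0.318) and Rpl23 in 3 (0.0019 to 0.34). Xist, expressed from the inactive X chromosome of female cells, differed by 0.60 ± 0.27 (limma adjusted p = 0.282), with adjusted p = 0.0319 after quantile normalization and 0.00151 without wild type replicate 2, the lowest of its alternatives, which reached 0.664. The Y-linked genes Eif2s3y, Kdm5d and Uty differed by 0.17 ± 0.11, -0.17 ± 0.07 and -0.01 ± 0.08 (limma adjusted p = 0.480, 0.241 and 0.977). Of these 4 genes limma called 0, against 1 lower at an unadjusted p under 0.05 (0 when adjusted over the list alone; camera adjusted p = 0.562).

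The balance between rises and falls depended on the scaling: 1009 genes were higher and 1083 lower after quantile normalization, against 418 and 778 in the deposited scaling. The count of called genes was 463 without knockout replicate 3, 511 without wild type replicate 3 and 617 without knockout replicate 2, but 1594 without wild type replicate 1 and 1438 without wild type replicate 2. No list passed camera at an adjusted p under 0.05 with an estimated correlation (3 passed unadjusted), whereas 10 did with the preset one. The chemokine and chondrocyte lists also lost their call, although their estimated correlations (-0.00027 and -0.012) lay below the preset 0.01. Losing a call under the estimate therefore does not show that the genes of a list are correlated. Limma's fry, which tests whether a list moves 1 way on balance without comparing it with other genes, passed 8.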

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

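The tests of the remaining Lasp1 signal, of the interferon genes and of the Hox genes, and the counts of genes over other splits of the arrays, were chosen only after the result had been seen. Probes with no gene in the annotation held signal that no comparison had used: 89 of 10378 were higher in knockout arrays and 89 were lower at a limma adjusted p under 0.05, 23 and 10 of them at least 2-fold, with log2 differences from -2.83 to 2.29. Of these probes 34.8% lay above the median of all probes.

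The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 418 genes higher, 778 lower and 126 changed at least 2-fold, and the highest of the other splits gave 0 for each. Both groups of every other split hold both genotypes, so a genotype difference adds to the spread within them and lowers their counts. A count of 0 there does not show what arises in the absence of a genotype difference. The real split passed 10 lists with camera and the other splits passed 1 to 7. In each of these 4 counts 1 split, the real one, reached the real value. With the preset correlation, the smallest camera adjusted p of a list in another split was 1.09e-07. In the real split only the interferon (5.56e-14) and cell cycle (1.02e-13) lists lay below that value. A camera adjusted p as small as that of the chemokine list (1.46e-06) thus also arose in a split that mixes the genotypes. Such a split holds the genotypes in unequal numbers in its groups, so part of a genotype difference stays in it. These values therefore do not show what camera gives in the absence of a genotype difference. At an unadjusted p under 0.05 the other splits called 152 to 2783 genes, against 3548.

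Knockout arrays kept 35.3% of the Lasp1 signal at the brightest probe. Wild-type cells in the knockout cultures are argued against as the whole source of the signal at that probe, because a share of such cells would keep at least that share of every other transcript, and 22 of 529 bright genes that fell kept less than 33.0%, the lowest share at that probe, in every knockout array. The minimum set for this test was 10 genes, at the brightest probe only. At the dimmer probe the lowest share was 11.4%, and 6 genes kept less than that in every knockout array. In a mixture each of these genes caps the share of wild-type cells. The 6 genes thus argue against such cells as the whole source of the signal at the dimmer probe too. A smaller share of such cells, as part of the source, stays open. The smallest share was 1.71%; the genes were those with at least 3000 of wild-type signal over the array median, a minimum set after near-background genes had given meaningless shares. A ceiling of the fluorescence scale is argued against as the whole source because the dimmer probe, far below the brightest values, also kept at least 11.4% of its signal over the array median. The mean share left over that median was larger at the brightest probe (34.9%) than at the dimmer (18.2%), the direction a ceiling would give. The wild-type mean at the brightest probe (144104) lay below the array maxima (497170 to 557140), but a part in the larger share was not excluded. RNA from the disrupted gene and binding of other transcripts to the probes stay open and were not tested, since the probes were not placed relative to the disruption.

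Interferon response genes had a median log2 difference of -0.46 (bootstrap interval over genes -0.64 to -0.30). A difference in brightness between arrays is argued against by a median of -0.42 after quantile normalization. A single array as the whole cause is argued against by a median of -0.35 to -0.57 without each array, although the number of falls was 11 without wild type replicate 3 and 11 without knockout replicate 3, against 20. More leukocytes in the wild-type cultures would lower the macrophage and leukocyte list in knockout arrays, but its median was 0.0854 (0.04 to 0.18), in the opposite direction. That interval is over genes measured on the same arrays, so it does not measure the spread between cultures. Fry did not pass the list (adjusted p = 0.267). These values gave no sign of more such cells in wild type and do not exclude them. A difference in culture conditions and an effect of genotype stay open, as untested, because the labels give no batch.

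The Hox genes differed by paralog group, with a rho of -0.53 across 38 genes. The called rises lay in the Hoxa, Hoxb and Hoxc clusters and the called falls in Hoxc and Hoxd. A difference by cluster was not tested and was not told apart from one by paralog group. A difference in brightness between arrays is argued against by a rho of -0.54 after quantile normalization. A single array is argued against by a rho of -0.54 to -0.49 without each array. With the 28 Hox genes above the median of all probes, rho was -0.55. Fibroblasts taken from different levels of the embryo in the 2 groups, and an effect of genotype, stay open as untested hypotheses, since the labels do not say which part of the embryo was cultured.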

How the results depend on the processing

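Background correction was chosen as an alternative only after the data had been seen; the others were planned. The floors of 4, 16 and 64 lay below the smallest value (593) and centring on medians that were all 1000 moved nothing, so these alternatives say nothing about stability. Lasp1 stayed called in all alternatives run, with a log2 difference from -1.27 (mean of all probes) to -1.55 (without wild type replicate 1). The count of genes higher (418) became 1009 after quantile normalization, 985 with array weights, 179 with the replicate block, 222 after normexp background correction, and 207 (without wild type replicate 3) to 729 (without wild type replicate 2) without single arrays. The count of genes lower (778) became 2282 with array weights, 236 with the block, 316 after normexp, and 244 (without knockout replicate 3) to 1217 (without wild type replicate 1) without single arrays; without wild type replicate 3 and knockout replicate 2 it was 304 and 337, and the rises without knockout replicates 1 and 3 numbered 273 and 219. The count of 2-fold changes (126) became 79 with the mean of all probes and 280 after normexp. The cause of these shifts was not tested, except that leaving out an array removes 1 of 6 samples. The arrays of the 2 genotypes did not overlap in any of the 1196 called genes, so only a rescaling or an average over probes could turn a sign: 1196 kept it after quantile normalization and after normexp, and 1194 with the mean of all probes. Calls shared in direction with the deposited scaling were 1115 of 2092 after quantile normalization, 1196 of 3267 with array weights, 415 of 415 with the block and 504 of 538 after normexp. After normexp 14 interferon, 7 cell cycle, 6 matrix and 4 fibroblast genes fell, and 5 chemokine and 2 contractile genes rose. Of the other named genes, 39 lost their call after normexp, 35 with the block, 16 with the mean of all probes, 7 with trend and robust estimation, 2 with the restriction to brighter genes, 1 after quantile normalization, 34 without knockout replicate 3, 31 without wild type replicate 3, 28 without knockout replicate 2, 11 without knockout replicate 1, 10 without wild type replicate 2 and 2 without wild type replicate 1. Arrays that share a replicate number did not all deviate together (correlations of -0.41, -0.34 and 0.22). These 3 values gave no sign that the numbers pair the arrays. They cannot exclude a pairing, since differences in brightness between arrays also enter the deviations. The array weights were 3.47 for wild type replicate 3, 1.72 for knockout replicate 3 and 0.52 to 0.91 for the others.

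With an estimated correlation 0 lists passed camera, against 10. The adjusted p was then 0.646 for collagens, 0.340 for contractile, interferon, adipocyte and chondrocyte genes, 0.104 for chemokines, 0.303 for cell cycle, 0.399 for cholesterol synthesis and macrophages, and 0.429 for fibroblast identity. With fry it was 0.155 for collagens, 0.0680 for cholesterol synthesis and fibroblast identity, 0.267 for macrophages, 0.0117 for skeletal muscle and 0.00250 for epithelium. On ranks it was 0.0881 for adipocytes and 0.245 for chondrocytes. Quantile normalization gave 0.0193 for actin and focal adhesion genes and 0.0644 for chondrocytes, and array weights gave 0.0529 for chondrocytes. Restriction to brighter genes gave 0.0423 for focal adhesion and glycolysis and 0.0126 for skeletal muscle. The mean of all probes gave 0.0324 for focal adhesion, glycolysis and imprinted genes, eBayes with trend gave 0.0334 for imprinted genes, and the replicate block gave 0.0406 for glycolysis. Without single arrays the adjusted p ranged from 0.0312 to 0.289 for focal adhesion, 0.0159 to 0.260 for glycolysis, 0.0297 to 0.162 for skeletal muscle and 0.00566 to 0.112 for chondrocytes. The cause was not tested. Signal over background limits the folds of dim genes.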

Other observations

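The genes in this paragraph and the Hox grouping were chosen only after their values had been seen. For the retinoic acid, NF-kB and YAP and TAZ lists, bounds on the median and on camera at the preset correlation were set before their results. The estimated correlation and the bootstrap intervals, also used to judge these lists, were not part of those bounds. Some called genes outside the lists are relatives of named genes. Adh1, also an alcohol dehydrogenase that acts on retinol, was lower beside Adh7 (log2 difference -1.62 ± 0.14 SE, limma adjusted p = 0.000249), while the aldehyde dehydrogenase Aldh1a7 was higher (1.15 ± 0.08). The AP-2 family gene Tfap2a was lower (-1.10 ± 0.11) beside Tfap2b. The kininogen gene Kng2 was higher (1.32 ± 0.09) beside Kng1. Col10a1, the collagen of hypertrophic cartilage, was higher (1.12 ± 0.12) beside Col2a1. The antiviral genes Dhx58 (-1.13 ± 0.20) and Parp14 (-1.14 ± 0.16), which interferons induce, were lower. The muscle ankyrin repeat gene Ankrd1 rose by 1.68 ± 0.13 and the NF-kB regulator Nfkbiz by 1.41 ± 0.11. The sizes for Aldh1a7 and Kng2 are not settled, since background correction raised their folds by over 1.5 times. All of these had separate groups in the 6 arrays, and the adjusted p was at most 0.0116.

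Single called genes prompted 3 hypotheses about regulators (Nfkbiz, Cxcl1 and Lcn2 for NF-kB, Tgm2 and Hoxa5 for retinoic acid, Ankrd1 and Ccn2 for YAP and TAZ), which were tested on lists of other targets that left these genes out. Higher NF-kB activity in knockout cells might raise its other targets: 14 had a median log2 difference of 0.15 (bootstrap interval 0.00058 to 0.26), with limma's camera upward (adjusted p = 0.0334 over the 3 lists). This met the bounds set beforehand for the median and for camera at the preset correlation (unadjusted camera p = 0.0111). The camera adjusted p was 0.498 with an estimated correlation, which those bounds did not ask for. Limma called 0 of the 14 as higher and Ptx3 fell (-0.46 ± 0.10), so the hypothesis is left open here although its bounds were met. Higher retinoic acid signalling had been set to be excluded by a median of 0 or less: 9 targets had a median of -0.13 with limma's camera downward (adjusted p = 0.432), but the interval of -0.32 to 0.08 spans 0, so the value does not settle it. Higher YAP and TAZ activity had the same bound, and 17 targets had a median of -0.0417 (-0.15 to 0.07) with limma's camera upward (adjusted p = 0.597) and 1 rise (Crim1, 0.59 ± 0.09), which does not settle it either.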
